A study of Homo sapiens with 12 samples.

How the data were processed

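Gene expression was measured from total RNA of PANC-1 cells on Illumina bead arrays, in 4 untreated samples, 4 given 1 µM tamoxifen for 48 h and 4 given 4 µM tamoxifen for 48 h. The sample titles give the lower dose as 1 µM, while the treatment notes print it with a unit of volume. The values deposited by the authors are probe intensities on a linear scale. Tested on the file, the 12 columns share 1 distribution up to ties, so they were quantile-normalized between arrays, and no background subtraction was apparent. The submitters' processing notes name GenomeStudio, whose version and settings are not given in the sources used here. A second table holds 12 value columns and 12 columns of detection p-values under names that match no sample label, so these 24 columns were not used.

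Groups and replicate numbers were taken from the sample titles. Of 47323 probes, 30113 were assigned 1 gene in the annotation supplied, 8 several genes and 17202 none, and 30074 had their gene in the reference list of symbols. Background was estimated on the intensities as the mode of their distribution (101.8) with a standard deviation from its lower side (15.8). A probe counted as above background on an array when its intensity exceeded the mode by 1.645 standard deviations (127.7, or 6.85 on the log2 scale used), and as detected when it did so on at least 4 of the 12 arrays. This left 22807 probes, 16804 of them with 1 gene. Each of the 3386 genes with several detected probes was represented by the probe with the highest mean, and probes without a gene stayed as features of their own, which gave 12451 named genes and 6003 unnamed probes, 18454 in all. Values were background-corrected by the normexp method on the signals alone with an offset of 50 and taken to log2.

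The fixed design had named normexp with negative controls from detection p-values (neqc) and a filter on detection p. Both need the unassigned columns, so the signal-only correction, which was among the alternatives fixed beforehand, and the background threshold above took their place. The groups, the comparisons, the tests, the 26 gene lists, the rule for named genes and the alternatives were otherwise fixed before the data were examined.

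Group means were fitted with limma (version 3.58.1, R 4.3.3) over all 12 arrays, with 9 residual degrees of freedom and 24 added by the empirical Bayes step, and the comparisons were each dose against untreated cells and 4 µM against 1 µM. Adjusted p-values are Benjamini-Hochberg values over the 18454 features of a comparison, two-sided, and a gene was called below 0.05. Errors are standard errors of the log2 fold change from that model. A gene below background on all arrays of 1 group is given as a bound against the background threshold, and one below it in both groups has no fold change. Gene lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 26 lists of a comparison. Camera with an estimated correlation and fry were run beside it. Fry asks whether a list's genes move one way on balance and does not compare them with other genes. No list was chosen on these samples. Since both doses share the untreated arrays, the correlation of their fold changes was set beside simulations of unchanged treated groups, and their overlap and correlation were computed again with the untreated arrays split 2 and 2.

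Named genes were, for each dose against untreated cells, the 10 largest rises and 10 largest falls among called genes whose 4 treated arrays all lay on 1 side of the 4 untreated arrays, and for 4 µM against 1 µM the 5 and 5 by the same rule. Up to 4 members of each list with the largest called change at 4 µM, else at 1 µM, were added, with 21 genes always given, which made 133 genes with values. Genes behind counts of 5 or fewer, the exceptions within a list, PHGDH, the genes with opposite calls at the doses and the members of gene families were named after their values were seen. PPP2R2B was the only named gene whose detected probes were called in opposite directions at 4 µM. No genome build or positions are given for the probes.

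The procedure was tested on simulated data, with changes added to the spread of the real arrays. It called 71.6% of 67 genes changed by a log2 fold of 0.5, 100% of 67 changed by 1 and 100% of 66 changed by 2, and 0.0329% of 18254 unchanged genes. The simulation changed few genes and drew the noise of each gene independently, whereas 7768 features were called at 4 µM in the real data. The threshold set by the adjustment depends on that number, so these shares do not carry over to the real comparisons. No 2 arrays held identical values. Replicate numbers did not pair the arrays, since the 12 pairs with the same number had residual correlations of -0.073 to 0.156 and 4 of 12 arrays correlated best with an array of their own number.

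The alternatives fixed beforehand changed the background correction together with its offset, the detection filter, the probes per gene, the arrays in the fit, the empirical Bayes settings, array weights, a replicate block and the list test, and left out each array in turn. An offset of 16 in the correction and a test of named genes only were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.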

Results

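Gene expression was measured on Illumina bead arrays in PANC-1, a human line from a pancreatic ductal adenocarcinoma, stably carrying an E47 that tamoxifen switches on. E47 is a basic helix-loop-helix transcription factor of the E-protein family, encoded by TCF3. The 12 arrays fall into 3 groups of 4, namely untreated cells, cells given 1 µM tamoxifen and cells given 4 µM tamoxifen, both doses for 48 h. The purpose stated for the series is to follow gene expression when E47 activity is induced. No group holds cells without the inducible E47 that were given tamoxifen. No time is recorded for the untreated samples, and their titles name no vehicle. A difference in either, if there was one, cannot be told apart from tamoxifen. The labels do not say whether the 4 replicates of a group are separate cultures, so the p-values measure only the spread between these samples, which may be technical. That number of arrays limits the precision of each value.

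The deposited intensities had a median of 119.9 to 120 on each array, and 21108 to 21141 probes per array lay above background. Both ranges are narrow because the values are quantile-normalized between arrays, so they say nothing about array quality. Across genes, which are not independent replicates, arrays of the same group correlated at 0.9906 or more, and no untreated array correlated with a treated array above 0.9575. The first principal component took 71.5% of the variance and set the untreated arrays, at -52.32 to -51.6, apart from the treated arrays, at 18.62 to 33.27. The second component took 7.89% and set 4 µM array 1 (-3.68) apart from the other 4 µM arrays (-17.04 to -14.24), and 1 µM arrays 2 and 4 (21.22 and 20.21) apart from 1 µM arrays 1 and 3 (9.08 and 7.62). The untreated arrays lay at -6.04 to 3.98 on it. The median standard deviation of a gene within a group was 0.15 (log2) in untreated cells, 0.16 at 1 µM and 0.14 at 4 µM.

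The array's detected TCF3 probe was lower in treated cells. Its log2 fold change was -0.79 ± 0.12, adjusted p = 1.76e-06 at 1 µM and -1.44 ± 0.12, adjusted p = 4.29e-12 at 4 µM (± standard error, n = 4 arrays per group). The 4 µM arrays were below 1 µM by 0.64 ± 0.12 (adjusted p = 0.000461). Whether the TCF3 probe reads the introduced transcript as well as the cell's own is not stated in the sources used here. Among the 133 genes picked by the rules for named genes, each call against untreated cells had the 4 treated arrays on 1 side of the 4 untreated arrays, except SCG2 and SOX9 at 4 µM. The rules required this of the largest rises and falls, so it is partly fixed by the choice of genes. Over all calls at 1 µM, it held for 2954 of 3577 higher and 3065 of 3862 lower features. At 4 µM it held for 3394 of 3918 higher and 3239 of 3850 lower features. ESR1, the estrogen receptor gene, stayed below background on all 12 arrays.

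In cells given 4 µM tamoxifen, genes of DNA replication and mitosis were lower than in untreated cells, and most CDK inhibitor and Notch genes tested, the ID genes, 3 trypsinogen genes and the elastase gene CELA3A were higher. CDKN1C, which encodes p57, an inhibitor of cyclin-dependent kinases (CDK), rose by a log2 fold change of 5.81 ± 0.12, adjusted p = 9.87e-29 (56.2-fold, n = 4 arrays per group, untreated signal above background on 3 of 4 arrays). CDKN1A, the gene of the CDK inhibitor p21, rose 14.5-fold (3.85 ± 0.11, adjusted p = 8.08e-25). UHRF1, which helps to maintain DNA methylation at replication, was 6.83 times lower (-2.77 ± 0.12, adjusted p = 3.33e-20). Of 18454 genes and unnamed probes tested, 3918 were higher and 3850 lower, among them 885 higher and 651 lower at least 2-fold and 79 higher at least 8-fold. Quantile normalization gives each array the same distribution, so counts and folds at either dose are relative to it. A shift of all genes together would not show.

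**Figure D1:**
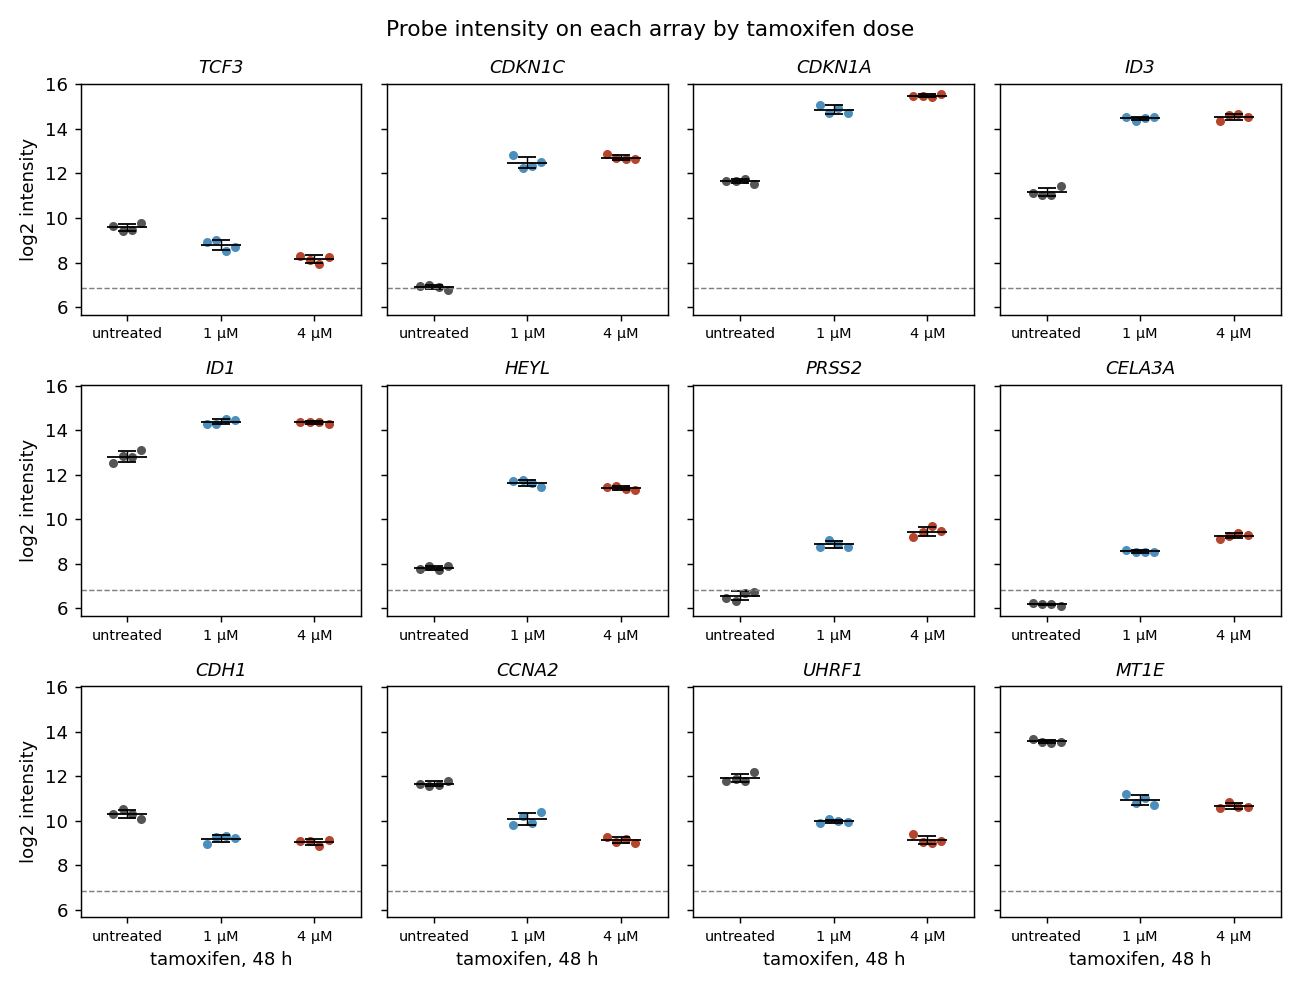
Log2 probe intensity of 12 named genes in untreated cells and at 1 and 4 µM tamoxifen (48 h), with a dot per array, the mean and its standard deviation (n = 4 per group), and a dashed line at the background threshold. The 4 TCF3 values lie at 9.43 to 9.77 in untreated cells and at 7.92 to 8.31 at 4 µM, and PRSS2 and CELA3A lie below the threshold on each untreated array.

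The replication list held 41 tested genes, of which 38 fell, ORC6 rose (0.37), and GINS1 (-0.30) and CCNE1 (0.03) did not pass the test (median log2 fold change -1.56, adjusted p = 7.22e-29, 1 higher and 39 lower adjusted over the list alone). Its larger falls were those of UHRF1, CDC45 (-2.54 ± 0.12), a part of the replicative helicase, EXO1 (-2.23 ± 0.11), a DNA repair nuclease, and TYMS (-2.17 ± 0.12), thymidylate synthase. All 44 tested genes of the G2/M and mitosis list fell (median log2 fold change -1.97, adjusted p = 1.47e-43, 44 lower adjusted over the list alone). With an estimated correlation between genes, camera gave a far larger adjusted p, 0.000648 for the mitosis list and 0.00036 for the replication list. Among them were the kinesin gene KIF20A (-2.49 ± 0.11), CDCA3 (-2.59 ± 0.11), cyclin A2 (CCNA2, -2.53 ± 0.12) and topoisomerase II alpha (TOP2A, -2.39 ± 0.12). MKI67, the proliferation marker Ki-67, was above background on every untreated array and on no 4 µM array, and was at least 1.6-fold lower. Here and elsewhere, a gene below background on every array of 1 group only is given as a bound, computed against the background threshold. Where an untreated mean lay under the threshold though some arrays lay above it, the values under it were set to it, and the fold is also given as a bound.

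Among CDK inhibitors and antiproliferative genes, 12 of 19 rose, CDKN2D (-0.83) and TOB2 (-0.44) fell and 5 did not pass (median log2 fold change 0.59, adjusted p = 2.31e-05, 12 higher and 3 lower adjusted over the list alone). Besides CDKN1C and CDKN1A, CDKN1B, which encodes p27, rose 4.14-fold (2.05 ± 0.11, adjusted p = 3.09e-17), and TP53INP1, a p53-induced stress gene, rose 4.96-fold (2.31 ± 0.11, adjusted p = 2.49e-18). The p53 target list had 11 of 22 genes higher and 4 lower (median log2 fold change 0.25, adjusted p = 0.00666, 11 higher and 4 lower adjusted over the list alone). Its largest rise was that of GDF15, a secreted stress cytokine (4.22 ± 0.10). TP53I3 stood at 1.07 ± 0.11, and DDB2, TRIAP1, PERP and CCNG1 fell, CCNG1 no longer so without 4 µM array 1 (adjusted p = 0.0513).

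The E-protein and ID list, which holds partners and known targets of E-proteins, had 12 of 17 genes higher, TCF3 and LYL1 (-0.38) lower and 3 not passing (median log2 fold change 0.85, adjusted p = 3.34e-08, 12 higher and 2 lower adjusted over the list alone). It shares CDKN1A and CDKN1C with the CDK inhibitor list and HES1, HEY1, NOTCH1 and NOTCH3 with the Notch list. CDKN1A and TP53INP1 are in both the CDK inhibitor and the p53 target list. The results of these lists are therefore not separate findings at either dose. The ID genes, whose proteins bind E-proteins and keep them from DNA, were higher, with ID2 at 3.63 ± 0.11, adjusted p = 7.37e-24, ID3 at 3.37 ± 0.11, adjusted p = 8.66e-23 and ID1 at 1.54 ± 0.12, adjusted p = 2.55e-13. In the TGF-beta and BMP list, which shares the 3 ID genes with it, 12 of 21 rose and 5 fell (median log2 fold change 0.50, adjusted p = 0.000948, median 0.36 with undetected genes at their bound, 12 higher and 5 lower adjusted over the list alone). CCN2, a matricellular growth factor, rose by 2.45 ± 0.11, and the activin antagonist FST was at least 5.15-fold higher. PMEPA1 (-1.31), TGFBI (-0.92), SMAD7 (-0.75), SMAD6 (-0.39) and LTBP2 (-0.37) fell. The call was lost for SMAD6 without 4 µM array 1 (adjusted p = 0.0743) and for LTBP2 without untreated array 1 or 4 µM array 1 (adjusted p 0.0805 to 0.112). This list's call was also lost when only probes above a stricter background level on all arrays were kept (adjusted p = 0.103, with a range of 2.02e-09 to 0.103 over its alternatives and the fits without an array). The Notch list had 13 of 21 genes higher, JAG1 (-1.35) and MFNG (-0.43) lower and 6 not passing (median log2 fold change 0.64, adjusted p = 4.55e-05, 13 higher and 3 lower adjusted over the list alone). The ligand gene DLL1 rose at least 12.6-fold (above background on 1 untreated array), the target gene HEYL by a log2 fold change of 3.58 ± 0.11 and HES2 by 2.60 ± 0.12, and the receptor gene NOTCH3 was at least 6.87-fold higher.

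Pancreatic lists moved in parts. Of the acinar enzyme genes, 8 were detected and 5 rose (median log2 fold change 1.14, adjusted p = 2.35e-05, median 0.89 with undetected genes at their bound, 5 higher adjusted over the list alone). These were the trypsinogen genes PRSS2 (at least 6.07-fold), PRSS1 (at least 2.19-fold) and PRSS3 (at least 5.23-fold, above background on 1 untreated array), the elastase gene CELA3A (at least 5.35-fold) and CUZD1 (0.65, above background on 3 untreated arrays). The lipase gene CEL did not pass (0.22 ± 0.12, adjusted p = 0.147), and the carboxypeptidase gene CPA1 stayed below background on all 12 arrays. Acinar and progenitor transcription factors had 3 of 11 genes higher (HES1 1.41 ± 0.11, XBP1 1.37 ± 0.11 and SOX9 0.34 ± 0.13) and 3 lower (HHEX -0.74 ± 0.11, FOXA2 -0.43 ± 0.12 and MNX1 -0.31). As a list they did not pass (median log2 fold change 0.01, adjusted p = 0.55, 0.01 with undetected genes at their bound, 3 higher and 3 lower adjusted over the list alone). The SOX9 call was lost without untreated array 1, 2 or 3 or 4 µM array 1 or 4 (adjusted p 0.0597 to 0.141) and with a smaller offset in the background correction (adjusted p = 0.0606, with a range of 0.00202 to 0.141 over its alternatives and the fits without an array). The MNX1 call was lost without untreated array 1 or 4, 4 µM array 1, 2 or 4 or 1 µM array 3 or 4 (adjusted p 0.0503 to 0.159). RBPJL did not pass (0.237 as its adjusted p), and PTF1A and BHLHA15, regulators of acinar identity, stayed below background on all arrays. Among ductal markers 10 of 16 rose, TSPAN8 fell (-0.73) and 5 did not pass (median log2 fold change 0.49, adjusted p = 0.000165, 10 higher and 1 lower adjusted over the list alone). LCN2, lipocalin 2, was at least 24-fold and the water channel gene AQP1 at least 7.23-fold higher, and KRT19, a ductal keratin, rose by 0.64 ± 0.12. Of 7 islet markers, SYP (at least 2.53-fold), CHGB (0.97 ± 0.12, above background on 3 untreated arrays) and SCG2 (at least 1.28-fold, on 2) rose, also adjusted over the list alone. That list did not pass (median log2 fold change 0.15, adjusted p = 0.0502). It fell under 0.05 without untreated array 2 (0.0268) or 3 (0.0467), 4 µM array 3 (0.0498) or 4 (0.0427), or 1 µM array 4 (0.0495), with a range of 9.05e-06 to 0.127 over its alternatives and the fits without an array.

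Epithelial junction genes went mostly up, with 13 of 19 higher, 4 lower and 2 not passing (median log2 fold change 0.64, adjusted p = 0.00119, 13 higher and 4 lower adjusted over the list alone). This list shares KRT8, KRT18, KRT19 and CLDN4, among others, with the ductal markers. Higher were the protease inhibitor gene SPINT1 (at least 4.8-fold), plakoglobin (JUP, 2.33 ± 0.13), the protease gene ST14 (at least 2.48-fold) and CLDN3 (1.67 ± 0.13), a tight junction claudin. Lower were CDH1, which encodes E-cadherin (-1.27 ± 0.12, adjusted p = 2.42e-11), LLGL2 (-1.11, above background on 2 of the 4 arrays at 4 µM), CLDN7 (-0.58) and PKP3, which was below background on each treated array. Mesenchymal genes went both ways, 11 higher and 9 lower of 29 tested, and the list did not pass (median log2 fold change 0.01, adjusted p = 0.55, 11 higher and 9 lower adjusted over the list alone). The collagen gene COL6A1 rose by 2.54 ± 0.13, thrombospondin 1 (THBS1) by 2.36 ± 0.12, and SNAI2, a repressor of CDH1, was at least 2.97-fold higher. Markers of other cell types did not pass as a list (median log2 fold change -0.01, adjusted p = 0.362, mean 0.22 against a median below 0, 4 higher and 2 lower adjusted over the list alone). COL1A1 (2.02 ± 0.12, above background on 3 untreated arrays), LUM (at least 1.52-fold), COL3A1 and HBA1 (both below background on each untreated array) rose, while the myeloid markers CD68 (-1.24 ± 0.12) and CD14 (-1.07 ± 0.12, above background on 3 of the 4 arrays at 4 µM) fell.

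Lysosome and autophagy genes rose together, 21 of 29 higher, 7 not passing and the galactosidase gene GLA (-0.48) lower (median log2 fold change 0.62, adjusted p = 1.28e-07, 23 higher and 1 lower adjusted over the list alone). GABARAPL1, an autophagosome protein, rose by 1.53 ± 0.10, the protease gene TPP1 by 1.39 ± 0.12 and acid sphingomyelinase (SMPD1) by 1.14 ± 0.12. In the ATF4 stress response list 17 of 28 rose, SHMT2 (-0.57) and SLC1A5 (-0.50) fell and 9 did not pass (median log2 fold change 0.41, adjusted p = 2.17e-05, median 0.33 with undetected genes at their bound, 18 higher and 2 lower adjusted over the list alone). The transcription factor gene ATF3 rose 10-fold (3.33 ± 0.11, adjusted p = 5.48e-23), and DDIT4, an inhibitor of mTORC1, by 2.30 ± 0.11. Of the unfolded protein response genes 11 of 24 rose and 11 did not pass (median log2 fold change 0.20, adjusted p = 0.0169, 11 higher and 3 lower adjusted over the list alone). WFS1 stood at 1.68 ± 0.10 and DNAJB9 at 1.19 ± 0.12. SRPRB (-0.41) and SDF2L1 (-0.33) fell, the latter no longer so without untreated array 3 or 4 (adjusted p 0.052 to 0.0609), and 4 genes fell without 4 µM array 1. Fatty acid synthesis genes were mostly lower, 9 of 14 down, ACSL1 (1.46 ± 0.12) and ACSS2 (0.44) up and 3 not passing (median log2 fold change -0.47, adjusted p = 0.0228, 2 higher and 10 lower adjusted over the list alone). For that list the adjusted p = 0.127 with an estimated correlation, and it also missed the threshold with the stricter background filter (0.0521, in a range of 5.9e-05 to 0.127 over its alternatives and the fits without an array). FADS2, a desaturase gene, fell by 1.05 ± 0.12 and stearoyl-CoA desaturase (SCD) by 1.03 ± 0.11. Ribosome biogenesis and MYC target genes fell in 23 of 31 cases, with 7 not passing and ornithine decarboxylase (ODC1, 1.27 ± 0.11) higher (median log2 fold change -0.51, adjusted p = 2.1e-05, 1 higher and 23 lower adjusted over the list alone). MYC itself fell by 1.05 ± 0.11.

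The remaining lists did not pass at 4 µM. Cholesterol genes went 6 up and 9 down of 20 (median log2 fold change -0.07, adjusted p = 0.55, 6 higher and 9 lower adjusted over the list alone). The isomerase gene EBP stood at -1.44 ± 0.11, ACAT2 at -1.42 ± 0.11 and INSIG1, a sterol sensor, at 1.19 ± 0.11, while HMGCS1 did not pass (-0.08 ± 0.12, adjusted p = 0.648). Hypoxia and glycolysis genes went 9 up and 6 down of 28 (median log2 fold change 0.06, adjusted p = 0.116, 9 higher and 6 lower adjusted over the list alone). With no detection filter this list passed (0.0171, with a range of 7.44e-07 to 0.244 over its alternatives and the fits without an array). NDRG1 stood at 3.72 ± 0.12 and adrenomedullin (ADM) at 1.86 ± 0.11. NF-kB inflammatory genes went 9 up and 6 down of 19 (median log2 fold change 0.09, adjusted p = 0.116, 9 higher and 6 lower adjusted over the list alone). The NF-kB list too passed with no detection filter (0.037, range 4.26e-07 to 0.436). Lymphotoxin beta (LTB) stood at 3.27 ± 0.12, the chemokine genes CXCL1 at 1.88 ± 0.17 and CXCL8 at 1.88 ± 0.12, and the inhibitor gene NFKBIA at -1.25 ± 0.11. Type I interferon genes went 7 up and 11 down of 26 (median log2 fold change -0.17, adjusted p = 0.344, 7 higher and 11 lower adjusted over the list alone). IFIT1 stood at -2.00 ± 0.13 and MX1 at 1.08 ± 0.12. Estrogen receptor target genes went 6 up and 6 down of 19 (median log2 fold change 0.09, adjusted p = 0.366, 6 higher and 6 lower adjusted over the list alone). The receptor kinase gene RET stood at 4.20 ± 0.11 and IGFBP4 at -1.51 ± 0.13. Apoptosis regulators went 7 up and 4 down of 25 (median log2 fold change 0.08, adjusted p = 0.246, 7 higher and 4 lower adjusted over the list alone). The BH3-only gene BMF was at least 5.5-fold higher, and PMAIP1 rose by 1.87 ± 0.12. BID (-1.51 ± 0.13), BAD (-0.59), CASP6 and BIRC2 fell, CASP6 no longer so without untreated array 4 or 4 µM array 1 (adjusted p 0.0507 to 0.064) and BIRC2 without untreated array 3 or 4 µM array 2 or 3 (adjusted p 0.0851 to 0.138). NRF2 and aryl hydrocarbon receptor genes had TIPARP (3.01 ± 0.10) and heme oxygenase 1 (HMOX1, 1.14 ± 0.11) higher and 6 of 16 lower, the quinone reductase gene NQO1 at -0.91 ± 0.11 (median log2 fold change -0.13, adjusted p = 0.344, 2 higher and 6 lower adjusted over the list alone).

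Outside the lists, the larger rises at 4 µM included PTGDS, prostaglandin D2 synthase (at least 37.2-fold), MAL (at least 31.6-fold), RAET1G, a ligand of the NKG2D receptor (at least 25.7-fold), and HTR3C, a serotonin receptor subunit gene (at least 24.6-fold). C11orf96 (5.24 ± 0.12, above background on 3 untreated arrays), the lysyl oxidase-like gene LOXL4 (5.07 ± 0.12), S100A8 (at least 23-fold, on 2 untreated arrays) and the receptor gene FGFR3 (4.64 ± 0.12) also rose. The larger falls were those of MXRA5 (-2.94 ± 0.11, adjusted p = 1.18e-21), the metallothionein gene MT1E (-2.91 ± 0.12), LXN, a carboxypeptidase inhibitor (-2.89 ± 0.12), the transcription factor gene FOXQ1 (-2.76 ± 0.10), SLC25A18 (-2.75 ± 0.11), the Wnt antagonist DKK1 (-2.73 ± 0.11) and NUDT1 (-2.73 ± 0.12). UPK1B, a uroplakin, fell below background on each treated array and was at least 6.07-fold lower at both doses. PPP2R2B is given by its brightest probe (-2.89 ± 0.12), since its detected probes were called in opposite directions at this dose. At 4 µM, 15 of 26 lists passed, and 14 of these passed with an estimated correlation between genes. Each of the 15 had a larger adjusted p with the estimated correlation than with the preset one.

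**Figure D2:**
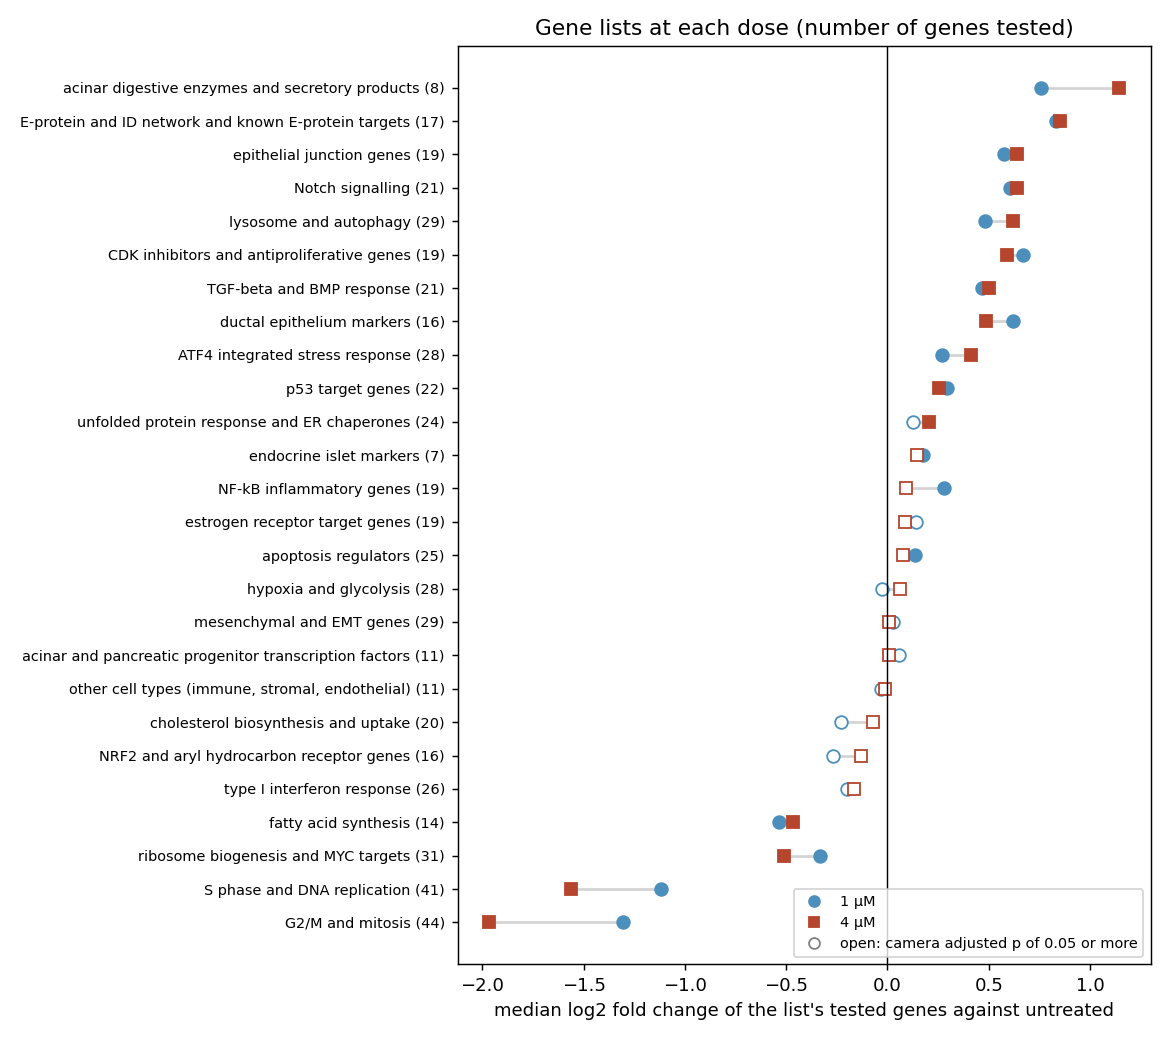
Median log2 fold change against untreated cells of each gene list at 1 and 4 µM tamoxifen, where an open point marks a list whose adjusted p was 0.05 or more. The G2/M and mitosis list has the lowest medians, -1.30 at 1 µM and -1.97 at 4 µM.

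In cells given 1 µM tamoxifen, the replication and mitosis genes were also lower than in untreated cells, and CDKN1C, CDKN1A, the ID genes and the trypsinogen genes were also higher. CDKN1C rose 48-fold (5.58 ± 0.12, adjusted p = 7.33e-28, n = 4 arrays per group), CDKN1A 9.39-fold (3.23 ± 0.11, adjusted p = 1.93e-22) and the stress cytokine gene GDF15 26.7-fold (4.74 ± 0.10, adjusted p = 1.84e-27). The larger falls were those of SLC25A18 (-2.72 ± 0.11), MT1E (-2.65 ± 0.12), MXRA5 (-2.57 ± 0.11) and SOX21, a neural transcription factor gene (-2.56 ± 0.11). In all, 3577 genes and unnamed probes were higher and 3862 lower, among them 742 higher and 455 lower at least 2-fold and 53 higher at least 8-fold.

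At this dose 38 of 41 replication genes fell and ORC6, E2F1 and CCNE1 did not pass (median log2 fold change -1.12, adjusted p = 9.86e-24, 39 lower adjusted over the list alone). All 44 mitosis genes fell (median log2 fold change -1.30, adjusted p = 3.66e-33, 44 lower adjusted over the list alone). With an estimated correlation, adjusted p = 0.00186 for the mitosis list and 0.000804 for the replication list. UHRF1 was at -1.93 ± 0.12, CDC45 at -1.68 ± 0.12, KIF20A at -1.93 ± 0.11 and CCNA2 at -1.60 ± 0.12. The CDK inhibitor list had 12 of 19 higher and CDKN2D lower (median log2 fold change 0.67, adjusted p = 1.65e-06, 12 higher and 1 lower adjusted over the list alone). CDKN1B stood at 1.73 ± 0.11. The p53 target list had 11 of 22 higher and CCNG1 and TRIAP1 lower (median log2 fold change 0.29, adjusted p = 0.000459, 12 higher and 2 lower adjusted over the list alone). The E-protein and ID list had 11 of 17 higher and TCF3 lower (median log2 fold change 0.83, adjusted p = 1.8e-08, 11 higher and 1 lower adjusted over the list alone). ID3 stood at 3.32 ± 0.11, ID2 at 3.25 ± 0.11 and ID1 at 1.57 ± 0.12. Notch genes were 13 up of 21, with JAG1, LFNG and MFNG down (median log2 fold change 0.60, adjusted p = 4.89e-06, 13 higher and 3 lower adjusted over the list alone). HEYL rose by 3.81 ± 0.11 and NOTCH3 was at least 5.57-fold higher. TGF-beta and BMP genes were 13 up of 21, with PMEPA1, TGFBI and SMAD7 down (median log2 fold change 0.47, adjusted p = 5.04e-06, 14 higher and 5 lower adjusted over the list alone), and 5 were down without untreated array 4. FST was at least 5.17-fold higher.

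The acinar enzyme list had 5 of 8 higher (median log2 fold change 0.76, adjusted p = 9.59e-05, median 0.51 with undetected genes at their bound, 5 higher adjusted over the list alone). These were PRSS2 (at least 4.07-fold), CELA3A (at least 3.28-fold), PRSS1 (at least 1.57-fold), PRSS3 (at least 4.68-fold, above background on 1 untreated array) and CUZD1 (0.36, on 3). Ductal markers were 9 up of 16 and TSPAN8 and ANXA4 down (median log2 fold change 0.62, adjusted p = 6.89e-05, 10 higher and 2 lower adjusted over the list alone). The ANXA4 call was lost without untreated array 3 or 1 µM array 2 or 4 (adjusted p 0.0997 to 0.14). LCN2 was at least 26.8-fold higher. Of the islet markers SYP, CHGB and SCG2 rose, also adjusted over the list alone (median log2 fold change 0.17, adjusted p = 0.0325). The list's adjusted p = 0.0864 with an estimated correlation and 0.0846 with no background filter (range 9.39e-06 to 0.0864 over its alternatives and the fits without an array). Acinar and progenitor transcription factors did not pass (median log2 fold change 0.06, adjusted p = 0.312, 4 higher and 3 lower adjusted over the list alone). HES1 (1.53 ± 0.11), XBP1 (1.06 ± 0.11), SOX9 (0.67 ± 0.13) and NR5A2 rose, NR5A2 not so without untreated array 4 (adjusted p = 0.0595). HHEX, MNX1 and PDX1 fell, MNX1 not so without untreated array 1 or 4, 4 µM array 2 or 1 µM array 2 or 3 (adjusted p 0.0501 to 0.196). PDX1, a pancreatic progenitor factor, was above background on each untreated and each 4 µM array and on no 1 µM array. Junction genes were 13 up of 19 and CDH1 (-1.12 ± 0.12), LLGL2 and PKP3 down (median log2 fold change 0.57, adjusted p = 6.97e-05, 13 higher and 4 lower adjusted over the list alone). JUP stood at 2.82 ± 0.13. Mesenchymal genes went 11 up and 9 down of 29 and did not pass as a list (median log2 fold change 0.03, adjusted p = 0.224, 0.02 with undetected genes at their bound, 11 higher and 9 lower adjusted over the list alone). Markers of other cell types did not pass (median log2 fold change -0.03, adjusted p = 0.483, mean 0.10), with COL1A1, COL3A1, LUM and HBA1 up and CD68 and CD14 down, also adjusted over the list alone.

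Lysosome and autophagy genes were 19 up of 29 and GLA down (median log2 fold change 0.48, adjusted p = 1.06e-06, 23 higher and 1 lower adjusted over the list alone). GABARAPL1 stood at 1.63 ± 0.10. NF-kB genes were 10 up of 19 and CCL2 and NFKBIA down (median log2 fold change 0.28, adjusted p = 0.000767, 0.25 with undetected genes at their bound, 10 higher and 2 lower adjusted over the list alone). CXCL8 stood at 2.45 ± 0.12. ATF4 response genes were 12 up of 28 and TRIB3, SHMT2 and SLC1A5 down (median log2 fold change 0.27, adjusted p = 0.00105, 14 higher and 3 lower adjusted over the list alone). The list had adjusted p = 0.0807 with an estimated correlation. Fatty acid synthesis genes were 8 down of 14 and ACSL1 up (median log2 fold change -0.54, adjusted p = 0.00444, 1 higher and 9 lower adjusted over the list alone). For this list, adjusted p = 0.0714 with an estimated correlation. Ribosome biogenesis genes were 16 down of 31 and ODC1 and RRP12 up (median log2 fold change -0.33, adjusted p = 0.00261, 2 higher and 16 lower adjusted over the list alone). Here adjusted p = 0.0548 with an estimated correlation. Apoptosis regulators were 9 up of 25 and BID, BAD and CASP6 down (median log2 fold change 0.14, adjusted p = 0.0498, 0.08 with undetected genes at their bound, 10 higher and 3 lower adjusted over the list alone). For the apoptosis list, adjusted p = 0.0714 with an estimated correlation. The apoptosis call was also lost without untreated array 2 (0.0664) or 3 (0.0566), 1 µM array 3 (0.0695) or 4 (0.0673), or 4 µM array 1 (0.0545), 2 (0.0522) or 3 (0.0519), with a range of 2.7e-06 to 0.158 over its alternatives and the fits without an array.

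The other lists did not pass at 1 µM. Unfolded protein response genes were 7 up of 24 and SDF2L1 and SRPRB down (median log2 fold change 0.13, adjusted p = 0.0695, 7 higher and 2 lower adjusted over the list alone), and the list passed with no detection filter (0.0244, range 2.45e-06 to 0.103 over its alternatives and the fits without an array). Cholesterol genes were 9 down of 20, with TM7SF2 (1.14 ± 0.12), SC5D and INSIG1 up (median log2 fold change -0.23, adjusted p = 0.163, 4 higher and 9 lower adjusted over the list alone). Hypoxia genes were 10 up and 7 down of 28 (median log2 fold change -0.03, adjusted p = 0.238, 10 higher and 7 lower adjusted over the list alone), the mean (0.24) and the test pointing up against a median below 0. Interferon genes were 12 down of 26 and ISG20, MX1, IRF9, ISG15 and IFI35 up (median log2 fold change -0.20, adjusted p = 0.354, 6 higher and 12 lower adjusted over the list alone). NRF2 genes were 8 down of 16 and TIPARP and HMOX1 up (median log2 fold change -0.27, adjusted p = 0.126, 2 higher and 9 lower adjusted over the list alone). Estrogen receptor targets had RET (3.31 ± 0.11), XBP1, CCND1, TFF3 and ADCY9 up and IGFBP4 and FKBP4 down (median log2 fold change 0.14, adjusted p = 0.182, 5 higher and 2 lower adjusted over the list alone), FKBP4 not so without untreated array 1 or 3 or 1 µM array 4 (adjusted p 0.055 to 0.197). At 1 µM, 17 lists passed, 12 of them with an estimated correlation.

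Both doses were compared with the same untreated arrays, so some likeness between them arises without any effect. In all, 2932 genes and probes were higher and 2959 lower at both doses, where independent lists, with no arrays in common, would share 759 and 806. Simulations of unchanged treated groups (20) shared at most 0, which carries no weight for the overlap, since unchanged genes are seldom called. With 2 untreated arrays given to each dose, 2253 to 2327 were higher and 2141 to 2232 lower at both over 6 such splits. CDKN1C, CDKN1A, ID2, ID3, HEYL, LOXL4 and GDF15 were among those higher, and UHRF1, CDC45, CCNA2, MT1E and CDH1 among those lower. Across genes, the log2 fold changes of the doses correlated at 0.934 (covariance 0.318), against 0.501 (covariance 0.00753) in 100 simulations without effect, and at 0.881 to 0.905 with split untreated arrays. Of those higher at both doses, 404 were higher still at 4 µM than at 1 µM and 141 were lower there, while of those lower at both, 339 were lower still and 36 higher.

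**Figure D3:**
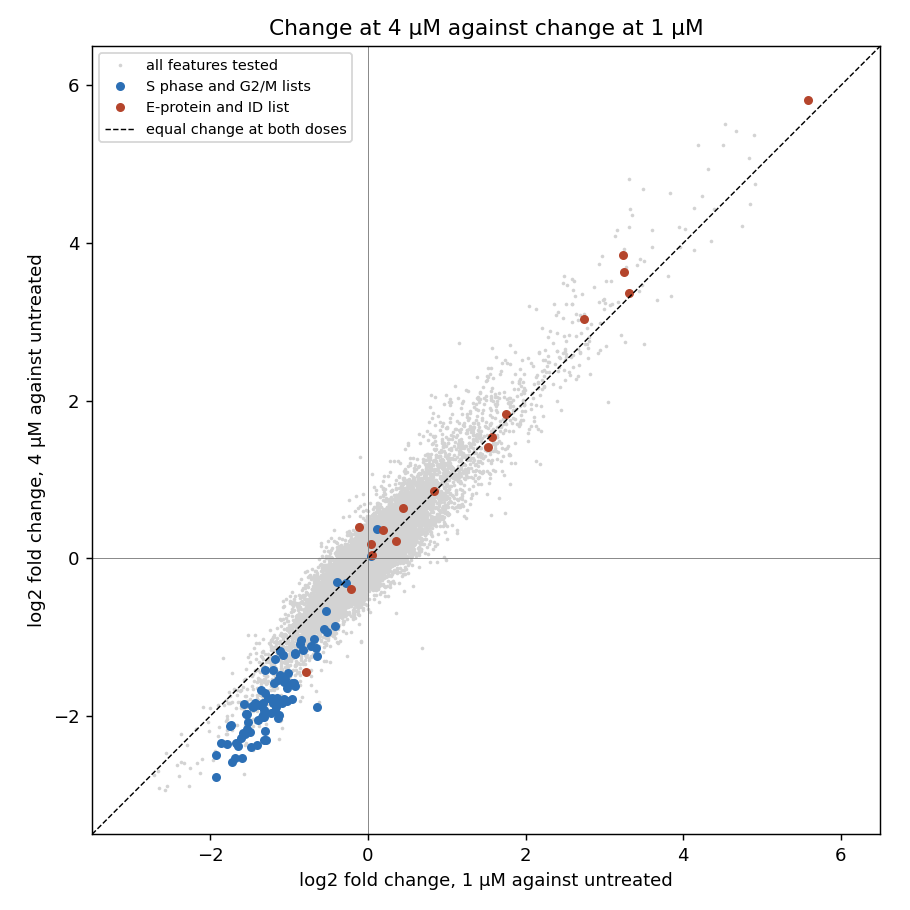
Log2 fold change against untreated cells at 1 µM (horizontal) and 4 µM tamoxifen (vertical) for each gene or probe tested, with the replication and mitosis lists in blue, the E-protein and ID list in red and a dashed line of equal change. The correlation across genes is 0.934, and the blue points lie mostly under the line.

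Between the doses, most mitosis genes and part of the replication genes were lower at 4 µM than at 1 µM, and the elastase gene CELA3A and the trypsinogen gene PRSS2 were higher. UBE2C, a ubiquitin-conjugating enzyme of mitosis, was lower by 1.23 ± 0.11 on the log2 scale (adjusted p = 7.36e-09, n = 4 arrays per group), a 2.35-fold difference. HTR3C, below background in untreated cells only, was 2.85-fold higher at 4 µM (1.51 ± 0.13, adjusted p = 4.1e-09), and S100A8, a calcium-binding protein of inflammation, 2.28-fold higher (1.19 ± 0.14, adjusted p = 7.04e-07). Other genes higher at 4 µM were SUSD3 (1.27 ± 0.13), the somatostatin receptor gene SSTR2 (1.20 ± 0.12), AQP1 (1.16 ± 0.12) and MAL (1.07 ± 0.12). Others lower were the kinesin gene KIFC1 (-1.17 ± 0.13), DKK1 (-1.16 ± 0.11), the scaffold protein gene AKAP12 (-1.16 ± 0.12) and RRAD, a small GTPase (-1.06 ± 0.12). AKAP12 was still above untreated cells at 4 µM (0.58 ± 0.12, adjusted p = 8.04e-05), a call lost when its detected probes were averaged (adjusted p = 0.126, with a range of 8.46e-06 to 0.126 over its alternatives and the fits without an array). In all, 892 genes and probes were higher and 879 lower, 20 and 12 of them at least 2-fold. These counts were 567 higher and 566 lower without 4 µM array 2. The lower count was 567 without 4 µM array 3, 569 without 4 µM array 4 and 576 without 1 µM array 4.

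The mitosis list was lower at 4 µM in 40 of 44 genes (median log2 fold change -0.66, adjusted p = 3.33e-49, 42 lower adjusted over the list alone). CCNA2 stood at -0.94 ± 0.12 and TOP2A at -0.91 ± 0.12. The replication list was lower in 27 of 41 (median log2 fold change -0.40, adjusted p = 3.37e-20, 1 higher and 31 lower adjusted over the list alone), and in 16 without 1 µM array 4. CDC45 stood at -0.86 ± 0.12 and UHRF1 at -0.84 ± 0.12. With an estimated correlation, adjusted p = 0.000768 for the mitosis list and the same for the replication list. NF-kB genes were lower in 8 of 19 (median log2 fold change -0.33, adjusted p = 0.00143, 4 higher and 10 lower adjusted over the list alone). CXCL8 stood at -0.57 ± 0.12 and NFKBIA at -0.53 ± 0.11, while CXCL2 and PTGS2 were higher. CXCL2 did not pass without 4 µM array 3 (adjusted p = 0.0534) and PTGS2 did not pass without 4 µM array 2, 3 or 4 or 1 µM array 2 or 4 (adjusted p 0.0547 to 0.105). The acinar enzyme list was higher (median log2 fold change 0.28, adjusted p = 0.00145, 4 higher adjusted over the list alone) through CELA3A (0.70 ± 0.10), PRSS2 (0.58 ± 0.12) and PRSS1 (0.48 ± 0.12), the last of which did not pass without 1 µM array 2 (adjusted p = 0.0593). These lists passed with an estimated correlation as well. Ribosome biogenesis and MYC targets were lower (median log2 fold change -0.17, adjusted p = 0.000695, 0 higher and 6 lower adjusted over the list alone). For this list, adjusted p = 0.0523 with an estimated correlation. Lower were MYC (-0.46 ± 0.11), CAD, RRP12, BYSL and NOP58. BYSL did not pass without 4 µM array 2 or 3 or 1 µM array 3 or 4 (adjusted p 0.0578 to 0.0662) and NOP58 without 4 µM array 1, 2 or 4 or 1 µM array 1, 2 or 3 (adjusted p 0.0561 to 0.127).

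Mesenchymal genes were lower in 6 of 29 and COL1A1 and SNAI2 higher (median log2 fold change -0.13, adjusted p = 0.0432, 2 higher and 6 lower adjusted over the list alone). Here adjusted p = 0.0704 with an estimated correlation. That call was lost without 1 µM array 1 (0.0536), 3 (0.0568) or 4 (0.0688) or 4 µM array 1 (0.0505) or 3 (0.0851), with a range of 0.00013 to 0.0851 over its alternatives and the fits without an array. TGF-beta and BMP genes were lower through PMEPA1 (-0.82), JUNB (-0.67), NOG (-0.60), TGFBI (-0.49) and SMAD7 (-0.33), and ID2 was higher. The call was lost for SMAD7 without 4 µM array 2 or 3 or 1 µM array 2, 3 or 4 (adjusted p 0.0518 to 0.135) and for ID2 without 4 µM array 3 or 4 or 1 µM array 2, 3 or 4 (adjusted p 0.056 to 0.076). That list's adjusted p = 0.0165 (median -0.11, 1 higher and 6 lower adjusted over the list alone), 0.0704 with an estimated correlation, 0.0505 without 4 µM array 1 and 0.124 with the mean of a gene's probes (range 0.00106 to 0.124 over its alternatives and the fits without an array). In the other 19 lists the change between the doses did not pass, and median, mean and test differed in sign in 3 of these, the acinar and progenitor factors, the islet markers and the estrogen receptor targets. Among single genes there, PHGDH, of serine synthesis, was higher at 4 µM (0.88, adjusted p = 2.97e-06). With no detection filter 5 of these lists passed, all higher at 4 µM, namely ATF4 (0.0129), lysosome (0.0179), cholesterol (0.0233), hypoxia (0.0354) and unfolded protein response genes (0.0428). The ATF4 and lysosome lists also passed without 1 µM array 2 (0.0303 and 0.0376) or 4 µM array 4 (0.0119 and 0.0239), and the unfolded protein response list without 1 µM array 2 (0.0378).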

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

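The tests of other splits of the arrays and those on the fall of the cell cycle genes were chosen after the results were seen, while those on the ratio of the doses were written down before they were run, after the pattern had been seen.

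Against chance, 35 splits of the 8 arrays of a comparison into 4 and 4 were counted, with the third group kept in the fit. Only the real split, 1 of 35, gave as many genes as it did in each comparison. That is the smallest share that 35 splits can give. Each other split also mixes the groups compared, so a difference between them counts there as spread within a group. The counts therefore do not exclude chance by themselves. A chance difference between single cultures cannot be excluded in this way, as the replicates are not known to be separate cultures. The real split called 7439 genes and probes at 1 µM (highest other split 0, at the same threshold of limma's adjusted p), 7768 at 4 µM (highest other 0) and 1771 between the doses (highest other 8).

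The fall of the replication and mitosis genes, 85 genes with a median log2 fold change of -1.21 at 1 µM and -1.83 at 4 µM, was the first pattern weighed. Normalization acting on genes of that brightness is argued against, since the median lay at percentile 0 of 10000 random lists matched on mean expression, whose lowest medians were -0.23 and -0.25. A single array is argued against too, since the highest median over the 12 fits without 1 array each and both doses was -1.193. Tamoxifen acting without the inducible E47 stays open and cannot be told apart from induced E47, as 0 arrays held cells without it that were given tamoxifen. A difference in time or vehicle stays open too, as neither is recorded for the untreated cells. A fall in proliferation that comes with the induced E47 may therefore be put forward only as a hypothesis.

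From 1 to 4 µM, the cell cycle genes changed further than the genes that rose, with a median ratio of the log2 fold changes of 1.44 (lower quartile 1.3) in 81 cell cycle genes lower at both doses. Saturation of bright probes is argued against as the whole cause, since the ratio was 1.1 in the 2588 genes higher at both doses with a mean below log2 12 at 1 µM, and 1.01 in the 344 brighter ones. The ratio of the cell cycle genes lay at percentile 100 of random lists of other falling genes matched on the change at 1 µM, whose highest ratio was 1.24. These lists were not matched on intensity. Genes already near background at 1 µM, such as SLC25A18, SOX21 and UPK1B, can fall little further, which holds their ratio down. A further fall of all genes with falls of that size therefore stays open where they have room to fall. The 10 genes of the E-protein and ID list higher at both doses had a ratio of 1.04. A dose dependence that differs between gene groups is a possible explanation, and why it would differ was not tested.

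In 11 genes and probes the doses differed in direction against untreated cells, each with a called difference between the doses. Higher at 1 µM and lower at 4 µM (log2 fold changes in that order) were ADCY9 (0.32 and -0.29, difference -0.606), OPN3 (0.28 and -0.32, difference -0.602), GBP4 (0.45 and -0.41, difference -0.868), H1-10 (0.35 and -0.69, difference -1.04), ABLIM1 (0.39 and -0.32, difference -0.707), SLC35F3 (0.29 and -0.30, difference -0.591), IL32 (0.57 and -0.34, difference -0.914) and ILMN_2382717 (0.33 and -0.32, difference -0.647). Lower at 1 µM and higher at 4 µM were OGT (-0.43 and 0.35, difference 0.789), ILMN_1701247 (-0.31 and 0.52, difference 0.834) and ZBTB42 (-0.36 and 0.26, difference 0.627). Most of these calls against untreated cells were lost when 1 array was left out, and only GBP4 kept both. At 1 µM the call was lost for ABLIM1 without untreated array 3 (adjusted p = 0.0575), H1-10 without untreated array 1 or 3 or 1 µM array 2 or 4 (adjusted p 0.0884 to 0.193), OPN3 without untreated array 2 or 3 or 1 µM array 1, 2 or 4 (adjusted p 0.0639 to 0.123), SLC35F3 without untreated array 1 or 3 or 1 µM array 2 (adjusted p 0.0611 to 0.0845), ILMN_1701247 without untreated array 1, 3 or 4 or 1 µM array 3 or 4 (adjusted p 0.0568 to 0.0933) and ILMN_2382717 without untreated array 1 or 1 µM array 2 (adjusted p 0.0598 to 0.105). At 4 µM it was lost for ABLIM1 without untreated array 2 or 4 or 4 µM array 1 or 2 (adjusted p 0.0555 to 0.186), ADCY9 without untreated array 3 or 4 or 4 µM array 1 or 3 (adjusted p 0.0542 to 0.108), IL32 without untreated array 3 or 4 or 4 µM array 1 or 3 (adjusted p 0.0582 to 0.0733), OGT without untreated array 1 or 4 µM array 2 (adjusted p 0.0564 to 0.0567), OPN3 without untreated array 1 or 4 µM array 2 (adjusted p 0.0587 to 0.0697), SLC35F3 without untreated array 2 or 4 µM array 3 or 4 (adjusted p 0.0651 to 0.0678), ZBTB42 without untreated array 2, 3 or 4, 4 µM array 1, 2 or 4 or 1 µM array 3 (adjusted p 0.0506 to 0.126) and ILMN_2382717 without untreated array 2 or 3 or 4 µM array 2 or 3 (adjusted p 0.0533 to 0.0891).

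Among the named genes, 1 array stood apart from the other 3 of its group in 28 of 399 cases (7.02%) by Dixon's gap ratio at its 5% level, where chance gives about 1 in 20 groups and all features gave 5.39%. The gap is given as a share of the range. In untreated cells the lowest array was array 1 for PRSS1 (0.852), RRAD (0.889) and TOP2A (0.893), array 2 for LCN2 (0.881) and array 4 for DNAJC3 (0.84), and the highest was array 2 for IFIT1 (0.832) and array 4 for GABARAPL1 (0.914). PRSS1, RRAD and LCN2 were below background on each of these untreated arrays. At 1 µM, array 1 was highest for C11orf96 (0.84) and ID2 (0.842) and lowest for HERC5 (0.895) and HES2 (0.869), and array 2 highest for MRTO4 (0.842) and lowest for CDS1 (0.876) and TP53I3 (0.865). At 4 µM, array 1 was highest for LCN2 (0.872) and ODC1 (0.959), array 2 highest for CCN2 (0.93), CDS1 (0.856), CEBPB (0.872) and MT1E (0.836), array 3 highest for KIFC1 (0.919), NUDT1 (0.836), NUPR1 (0.937) and PRSS1 (0.848) and lowest for CDH1 (0.845) and SCG2 (0.838), and array 4 highest for PMAIP1 (0.87) and lowest for CD14 (0.954).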

How the results depend on the processing

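The offset of 16 in the correction and the test of named genes only were chosen after seeing the data. No result reversed. Against untreated cells the counts of genes stayed within 1.5 times in each alternative and each fit without 1 array: 2792 to 4415 higher and 2941 to 4829 lower at 1 µM (3317 to 3603 and 3507 to 3887 without 1 array), and 3055 to 4800 and 2946 to 4937 at 4 µM (3546 to 4002 and 3457 to 3937). Between the doses they were 672 to 1032 higher and 659 to 1085 lower, and 567 to 968 and 566 to 955 without 1 array. Shared calls were 2253 to 3002 higher and 2141 to 3056 lower (2735 to 2946 and 2716 to 2913 without 1 array). With the replicate number as a block, counts were 3629 higher and 3905 lower at 1 µM, 3947 and 3894 at 4 µM and 928 and 922 between the doses as a fixed effect. As a random effect they were 3596 and 3876, 3938 and 3876, and 908 and 896.

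Lists called without 1 array were 16 to 17 at 1 µM, 15 to 16 at 4 µM and 5 to 10 between the doses. Between the doses, 12 lists were called with no detection filter, 4 with an estimated correlation and 14 with fry, against 7. Fry called 26 at 1 µM and 25 at 4 µM, since it does not compare a list with other genes. For the filter and the estimated correlation the cause was not tested. Among 314 called results of named genes, 14 were not called in at least 1 alternative or fit without an array.

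Median scaling was not run, as the values are already quantile-normalized, nor were negative controls and the second table, whose columns match no label, nor a slide block, as no slides are named. Signal over background limits the folds of genes undetected in 1 group to bounds, and 1 threshold serves all arrays.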

Other observations

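All tests in this part were chosen after the data were seen. Beyond the fixed lists, 393 families of gene symbols with at least 5 tested genes were tested with camera over all families, and those described here kept the sign of their median under 4 transformations of the values. None of them passed with an estimated correlation. A family is a shared symbol stem, so its test also took in pseudogenes and antisense RNAs, 1 in the MT1 and MT2 family and 2 each in the MRPL and KRT families.

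Metallothionein genes, whose proteins bind zinc and copper, were lower, with 4 of 5 protein-coding MT1 and MT2 genes down at 1 µM and 3 at 4 µM (adjusted p = 0.0012 and 0.00541 at 1 and 4 µM, 0.12 and 0.182 with an estimated correlation). MT2A fell by 2.59 ± 0.12 and MT1G by 2.59 ± 0.12 on the log2 scale at 4 µM (n = 4 arrays per group), beside MT1E, while MT1X fell at 1 µM (-0.53 ± 0.11) and did not pass at 4 µM (-0.23 ± 0.11). In the MRPL family, of large mitochondrial ribosome subunit genes, 30 of 48 protein-coding genes fell at 1 µM and 25 at 4 µM (adjusted p = 0.000152 and 0.00367 at 1 and 4 µM, 0.209 and 0.318 with an estimated correlation). MRPL12 stood at -0.71 ± 0.13 and -0.93 ± 0.13, and the pseudogene MRPL42P5 rose at 4 µM (0.42 ± 0.12). In the NUP family, mostly nuclear pore genes, 13 of 22 fell at 1 µM and 15 at 4 µM (adjusted p = 0.00542 and 0.000737 at 1 and 4 µM, 0.209 and 0.169 with an estimated correlation). NUP107 stood at -1.23 ± 0.13 and -1.36 ± 0.13.

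Keratin (KRT) genes were higher in 8 of 10 protein-coding genes at both doses (adjusted p = 9.98e-05 and 0.000737 at 1 and 4 µM, 0.0652 and 0.113 with an estimated correlation). KRT15 stood at 1.64 ± 0.11 and 1.96 ± 0.11 and KRT80 at 1.80 ± 0.12 and 0.95 ± 0.12. Among the keratin genes that rose, KRT7, KRT8, KRT18 and KRT19 are also in the ductal list. Of 7 CXCL chemokine genes 6 rose at each dose (adjusted p = 0.0012 and 0.000737 at 1 and 4 µM, 0.12 and 0.113 with an estimated correlation), among them CXCL8, CXCL1 and CXCL16 (0.71 ± 0.11 and 0.55 ± 0.11). CXCL1, CXCL2, CXCL6 and CXCL8 are also in the NF-kB list, which passed at 1 µM and not at 4 µM. The keratin and CXCL results are therefore not separate findings from those lists. CXCL2 did not pass at 1 µM without untreated array 1, 3 or 4, 4 µM array 1, 2 or 4 or 1 µM array 2, 3 or 4 (adjusted p 0.0502 to 0.14). TLE genes, of the Groucho-related family, were higher in 5 of 6 at each dose (adjusted p = 0.00232 and 0.00616 at 1 and 4 µM, 0.137 and 0.182 with an estimated correlation). TLE6 stood at 2.09 ± 0.11 and 2.44 ± 0.11 (above background on 3 untreated arrays), TLE2 was at least 6.26-fold and 7.68-fold higher (on 1), and TLE3, TLE4 and TLE5 also rose.

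Across all features, 266 were above background on all 8 treated arrays and on no untreated array, 223 of them named genes, and 44 were above it on all 4 untreated arrays and on no treated array, 34 of them named genes.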
